A study of Drosophila melanogaster with 8 samples.

How the data were processed

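Total RNA of dechorionated whole embryos was measured on Affymetrix Drosophila Genome 2.0 arrays, a platform of short oligonucleotide probe sets that mostly lie toward the 3' end of transcripts. Per the labels, flies were reared at 25 °C and eggs collected at 18 °C to limit lethality, RNA was purified on columns, and biotin-labelled cRNA made from double-stranded cDNA was hybridised. The dimm embryos carried UAS-dimm (line 2A3) and elav-GAL4, each in 1 copy, and the control embryos came from the elav-GAL4 parental line, so the control differs from the dimm embryos also in the dose of GAL4 and in the paternal chromosomes. Stage 16 embryos were 28 to 32 h old. Stage 14 embryos were 22 to 26 h old per the sample labels, while the series text gives 24 h as the lower age. Each of the 4 groups had 2 arrays, numbered by the labels.

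The deposited table holds log2 values that the authors made with GCRMA, a method that corrects the background with probe sequence, quantile-normalises the arrays and summarises each probe set. Per the submitters' processing notes this was done with GCRMA 2.22.0 in R 2.12.1, with limma named without a version. Whether all arrays were processed together is not given in the sources used here. The lowest value differs between the stages and is shared by the 4 arrays of a stage, which is what separate processing of the stages would leave. A value at that floor is background, so a change from it has an uncertain size. Signals of dim transcripts in a whole embryo, such as neuropeptides made by a few cells, lie close to it.

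The table has 18952 probe sets. The 183 control probe sets were left out of the tests, and of the other 18769, 13646 named 1 gene, 402 several and 4721 none in the platform annotation. The single-gene probe sets named 11981 genes. Of these, 103 gene identifiers were not found in the RefSeq gene table of Release 6 plus ISO1 MT, which was used for names and for which genes neighbour each other, not for positions. A probe set with no name is unnamed here, not without a gene. No probe set named the white gene, which marks transgenes, so its result is not reported here.

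Probe sets above 4 on the log2 scale on at least 2 of the 8 arrays were tested, 8258 in all. limma 3.58.1 in R 4.3.3 fitted the 4 group means (4 residual degrees of freedom, 1.45 prior degrees of freedom) with default empirical Bayes moderation, and Benjamini-Hochberg adjustment ran over the tested probe sets with a threshold of 0.05. Contrasts were dimm over control averaged over the stages, at each stage, the difference of that effect between the stages, and stage 16 over stage 14 in each genotype. Errors beside log2 changes are standard errors of the fit. A gene is represented by its single-gene probe set with the highest mean over the arrays. On simulated data of 8258 probe sets, the average contrast recovered 70% of changes of 1 log2 unit and 90% of changes of 2, with 5 false calls among 165. Stage 14 recovered 52% and 81%, and stage 16 53% and 84%. The simulated arrays had independent noise and 1 spread per probe set in all groups. The real arrays did not: the SD of the difference between control arrays was 0.165 at stage 14 and 0.798 at stage 16. The simulation therefore does not show how recovery or false calls differ between the stages.

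Before the data were examined, 25 gene lists were fixed: neuropeptide precursors, neuropeptide processing and dense core vesicle genes, further candidates linked to dimm, secretory pathway machinery, unfolded protein response and ATF4 targets, transmitter and synaptic genes, pan-neuronal and ion channel genes, neuronal identity factors, markers of glia, neuroblasts, cell cycle, cell death, heat shock, muscle, epidermis and cuticle, fat body, haemocytes, midgut, germline, trachea and sense organs, antimicrobial peptides, ribosomal proteins, proteasome, and sex chromosome dosage. The 22 lists with at least 3 tested genes went through camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. On simulated data camera called the list that had been raised and did not call the unchanged list. The simulated genes were independent, so this does not check the preset correlation. Genes were named by a rule also fixed then: dimm first; the 12 largest rises and 12 largest falls past the threshold with the arrays of both stages not overlapping; the 5 largest each way past the threshold for single stages and for the stage change in control embryos, with arrays not overlapping, and for the difference between stages; up to 4 members past the threshold of each list; and Phm, CG1275, CG13248, mael, crc, elav and white whatever their result.

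The labels number the replicates alike in all groups. Deviations of same-numbered arrays from their group means correlated across probe sets at 0.906 between genotypes at stage 16 and at 0.155 at stage 14, against -0.0241 to 0.134 across stages. Sharing is thus clear at stage 16 only, from the data and not from the labels, and the stage 14 value is close to those across stages. A fit with 1 replicate term in each stage is given beside the counts it moves most, and its stage 14 term rests on a pairing with little evidence. The added calls at stage 14 do not need that pairing. A term for stage 16 alone gave 312 calls at stage 14, against 157 with both terms. Arrays of a group correlated at 0.9995 (control, stage 14), 0.998 (dimm, stage 14), 0.9881 (control, stage 16) and 0.991 (dimm, stage 16). Both stage 16 replicate 1 arrays had low signal at the 5' ends of control transcripts.

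Alternatives fixed at the same time were no filter, a filter at 6, an intensity trend or robust moderation, the replicate number as 1 term, the arrays of a group averaged, only the arrays of the groups compared, median centring, signals under 4 set to 4, array weights, only specific named probe sets, an additive fit, a 2-fold minimum and each array left out. The replicate term within each stage, a batch term for stage 16 and leaving out both low 5' arrays were added after the data were seen.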

Results

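The series profiled whole Drosophila embryos in which the transcription factor DIMMED (gene dimm) was switched on in all neurons. DIMMED is a basic helix-loop-helix factor that is normally restricted to peptide-secreting neuroendocrine cells, where it promotes the production, processing and storage of neuropeptides in dense core vesicles. A myc-tagged dimm transgene under UAS control was crossed to elav-GAL4, a driver active in neurons, and the progeny were compared with embryos of the driver line alone. The effect of dimm below means the difference between these groups, which also differ in GAL4 dose and paternal chromosomes. Embryos were taken at stage 14 and at stage 16, with 2 Affymetrix Drosophila Genome 2.0 arrays for each genotype at each stage, 8 arrays in 4 groups. The values are log2 GCRMA signals of probe sets. Between 7574 and 7651 probe sets lay above 4 on the log2 scale on each array, and 38.4% to 41.1% of probe sets sat at the lowest value of the arrays of their stage. The number of arrays limits the precision of every value below. The series text can be read as a pair of arrays for each RNA sample, so the p-values measure the spread between arrays, which may be technical.

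The transgene's own gene was higher in every dimm array. The dimm signal was 2.83 in control and 7.62 in dimm embryos at stage 14 (means of 2 arrays each), and 2.61 and 6.89 at stage 16. Averaged over the stages it rose by 4.54 ± 0.59 (SE, log2, 4 arrays against 4), a 23.2-fold difference with an adjusted p of 0.0386 in limma. The stage 16 dimm arrays differed from each other, at 5.51 in replicate 1 and 8.26 in replicate 2, and neither stage alone passed the threshold (adjusted p = 0.157 at stage 14 and 0.176 at stage 16). With all signals below 4 raised to 4, the average change of dimm was 3.26 with an adjusted p of 0.0867. The signal of elav, the neuronal gene whose promoter drives GAL4, differed by 0.02 ± 0.06.

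The main comparison asked which transcripts changed with pan-neuronal dimm over both stages. Phm, which encodes the peptide amidating enzyme PHM of neuropeptide synthesis and is a known target of DIMMED, rose 2.08-fold (log2 1.06 ± 0.12, adjusted p = 0.0272), from 10.44 to 11.42 at stage 14 and from 9.97 to 11.10 at stage 16. With the replicate pairs as a block Phm passed at each stage alone too (adjusted p = 0.0385 at stage 14 and 0.0332 at stage 16). Its other probe set differed by 1.31 with an adjusted p of 0.0681, and of 0.0158 with the block. With the block that probe set had an adjusted p of 0.0393 at stage 14 and 0.0507 at stage 16. CG13248, a cationic amino acid transporter gene, rose on average by 3.68 ± 0.19 on the log2 scale (adjusted p = 0.0054), by 4.56 at stage 14 and 2.79 at stage 16. Its control mean at stage 14 was 3.06, and with signals below 4 raised to 4 its average rise was 3.21. The gene mael, which encodes the piRNA pathway protein Maelstrom, rose 10.4-fold (log2 3.38 ± 0.23, adjusted p = 0.00715). At stage 14 alone mael differed by 2.25, with an adjusted p of 0.1 and of 0.0467 with the replicate pairs as a block. CG1275, a cytochrome b561 family gene, differed by 0.80 ± 0.15 and did not pass (adjusted p = 0.098), but passed with the replicate pairs as a block (adjusted p = 0.0134). The signal of crc, which encodes the fly ATF4, differed by -0.16 ± 0.10 (adjusted p = 0.707).

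The largest rises were those of Hrb87F, which encodes an hnRNP RNA-binding protein (log2 5.98 ± 0.13), GILT3, a thiol reductase family gene (5.78 ± 0.11), and Rnf11, a RING finger gene (32.1-fold, with a log2 change of 2.94 ± 0.19 in its second probe set). CG8745 (2.59), the transmembrane gene kek5 (2.57) and Lime (2.53) also rose on average, with higher means at both stages. CngA, a cyclic nucleotide-gated channel gene (3.18), CG33258 (2.44) and CG4577 (2.68) rose on average with very different sizes at the stages. In control embryos at stage 14, CngA and CG4577 lay at the lowest value of the table, so the size of their changes depends on that floor. With signals below 4 raised to 4, the average changes were 5.11 for GILT3, 2.23 for CngA, 1.97 for CG4577 and 1.76 for CG33258, all still past the threshold.

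**Figure D1:**
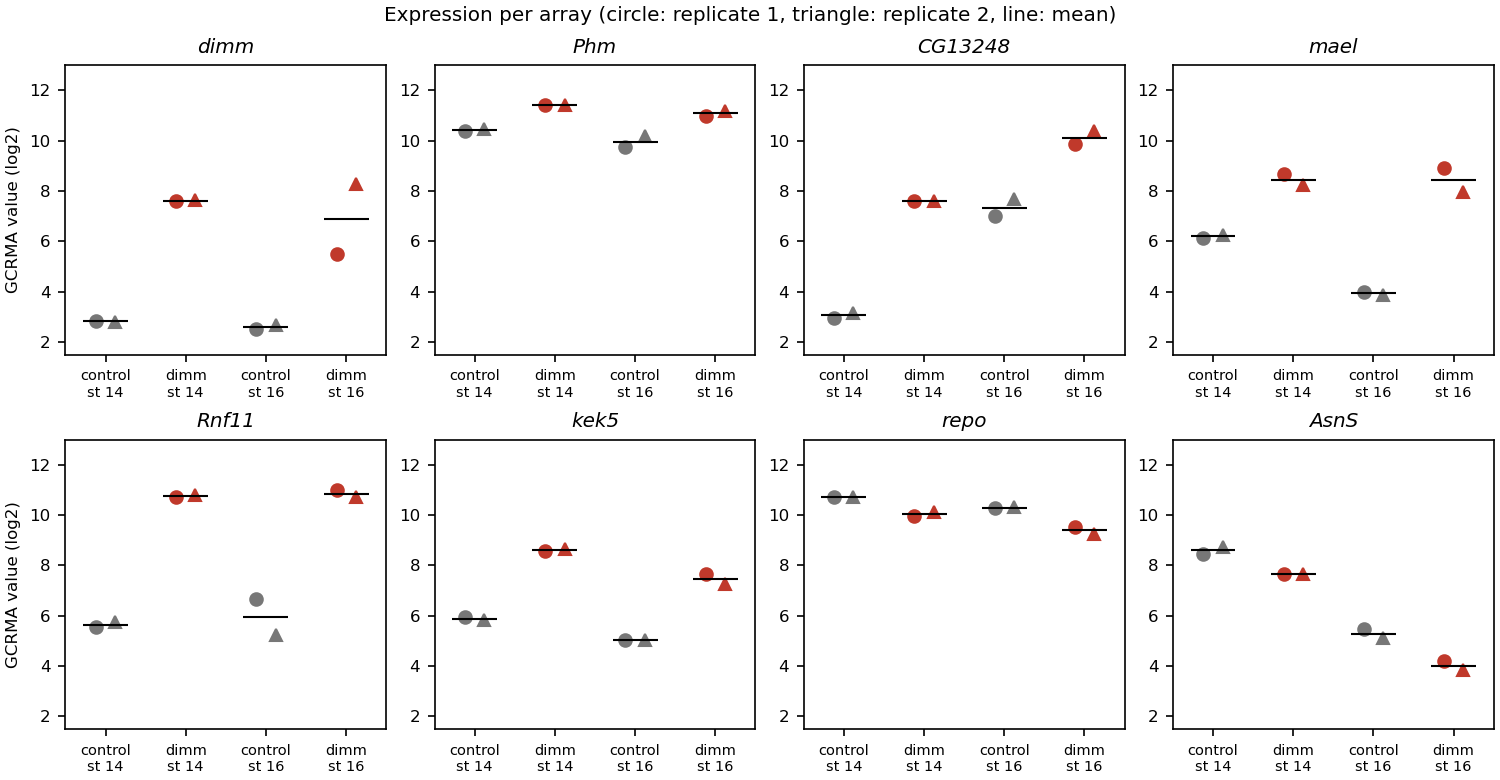
Log2 GCRMA signal of dimm, Phm, CG13248, mael, Rnf11, kek5, repo and AsnS on each of the 8 arrays, control in grey and dimm in red, with circles for replicate 1, triangles for replicate 2 and lines for the means of 2 arrays. The stage 16 dimm arrays lie at 5.51 and 8.26 for dimm, and in each panel both dimm arrays of a stage lie on one side of both control arrays.

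The falls were smaller. TM4SF, a tetraspanin family gene, fell by 1.71 ± 0.17 on the log2 scale, to 0.305 of the control level, and GstE1, a glutathione S-transferase gene, fell by 1.18 ± 0.07 (adjusted p = 0.0059). AsnS, the gene for asparagine synthetase, fell by 1.10 ± 0.13, the serine protease gene SPE of the Toll pathway fell by 1.09 ± 0.15, the serpin gene Spn42De fell by 1.33 ± 0.17, and mre11, a DNA double-strand break repair gene, fell by 1.28 ± 0.18. CG13532, lncRNA:CR32368, CG9449, CG31445, CG3588 and the odorant-binding protein gene Obp56a completed the 12 largest falls, with changes from -1.57 to -0.93.

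Across the 8258 probe sets tested, 124 passed an adjusted p of 0.05 in limma, 80 higher and 44 lower in dimm embryos. They named 72 genes that rose and 35 that fell. Of the 124, 39 were at least 2-fold higher and 14 at least 2-fold lower. Among all 8258, without selection, 994 had all dimm arrays beyond all control arrays in the same direction at both stages, a pattern that chance gives 5.56% of probe sets if all arrays are independent, which arrays of 1 RNA sample or of a shared replicate effect are not. At stage 16 the replicate 1 arrays of both genotypes had low signal at the 5' ends of the control transcripts. With the replicate pairs of each stage as a block, 639 probe sets passed, 367 higher and 272 lower, with the 124 among them. Leaving out both low 5' arrays gave 816 probe sets, of which 106 were among the 124, with 1 array against 1 at stage 16 and the spread taken from the stage 14 arrays. Leaving out any single array gave 4 to 66, and averaging the arrays of a group, as if each pair were 1 RNA sample, gave 3. None of the falls passed with the arrays averaged or without either control array of stage 14, where the 3 and 4 probe sets left were all higher.

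Among 13 neuropeptide processing and dense core vesicle genes, 1 was higher in dimm embryos (Phm) and none was lower, while 4 were higher when adjusted over the list alone. Over all genes, 4 were higher with the replicate pairs as a block (Phm, CG1275, 7B2 and Rph), and without the low 5' arrays 3 were. Changes were positive in 9 and negative in 4, with a median of 0.34. Members that did not pass over all genes without the block included Rph (1.33, adjusted p = 0.0766, and 0.0403 with the block), Pal2 (1.28, adjusted p = 0.106, and 0.051 with the block) and amon, the prohormone convertase gene (0.70, adjusted p = 0.511, and 0.0727 with the block). The list was higher as a set by camera with its preset correlation (adjusted p = 0.0194), and not with an estimated correlation (adjusted p = 0.508), with the replicate pairs as a block (adjusted p = 0.0691) or without the low 5' arrays (adjusted p = 0.137). Phm and CG1275 are also among the further candidates linked to dimm, which were drawn in part from published work, so this list is not wholly independent evidence either. Only 6 of 37 neuropeptide and peptide hormone precursors with a probe set were bright enough to test. None of the 6 passed over all genes and 1 was lower when adjusted over the list alone, with 3 positive and 3 negative changes. Among 37 genes of the secretory pathway machinery, none passed (median 0.01).

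Of 8 further candidates linked to dimm, 5 rose (Phm, CG13248, mael, Rnf11 and Tes, the last by 1.09 ± 0.16 with an adjusted p of 0.0468), none fell, and 7 were higher when adjusted over the list alone, as many as over all genes with the replicate pairs as a block. The set test gave an adjusted p of 3.07e-10 with the preset correlation and an adjusted p of 0.0482 with an estimated correlation. This list was drawn up in part from what is known of published work on these samples, so it is not independent evidence of its direction.

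Among 15 genes of the unfolded protein response and of ATF4 targets, 13 had negative changes. One member passed over all genes: aay, the phosphoserine phosphatase gene of serine synthesis, fell by 0.61 ± 0.06 (adjusted p = 0.023), 3 were lower when adjusted over the list alone, and 2 were lower over all genes with the replicate pairs as a block. The set was lower with the preset correlation (adjusted p = 0.0194) and not with an estimated correlation (adjusted p = 0.68), with the replicate pairs as a block (adjusted p = 0.0691) or without the low 5' arrays (adjusted p = 0.137).

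Neuronal genes as groups did not pass. None of 18 genes of small-molecule transmitters and synaptic vesicle release and none of 16 pan-neuronal and ion channel genes passed, with medians of -0.05 and 0.00. Of 19 neuronal identity transcription factors the only one past the threshold was dimm itself. Among 10 glial markers, repo, the homeobox gene required for glial differentiation, fell by 0.78 ± 0.08 (adjusted p = 0.0256), and the other 9 did not pass, with 6 of the 10 changes positive. Among 12 neuroblast markers, pros, a homeobox gene of neural precursor differentiation, rose by 0.48 ± 0.07 (adjusted p = 0.0476). In markers of other tissues, 1 of 20 epidermis and cuticle genes rose (Cpr49Ac, 0.66 ± 0.09; neither it nor pros passed after each array was centred on its median), and 1 of 8 germline and maternal markers rose, which was mael. No member passed among 15 cell cycle genes, 6 cell death genes, 4 heat shock genes, 13 muscle markers, 5 fat body markers, 11 haemocyte markers, 3 midgut markers, 7 tracheal markers, 2 sensory organ genes, 1 antimicrobial peptide gene, 35 cytoplasmic ribosomal protein genes, 26 proteasome genes and 2 genes of sex chromosome dosage. None of these lists passed camera (adjusted p from 0.615 to 0.931 for those tested). By unadjusted p under 0.05, 994 of the 8258 probe sets were counted in this comparison. Members of several of these lists passed with the replicate pairs as a block: 1 transmitter and synaptic gene was higher (Rim) and 2 were lower (ChT and Rop), 1 pan-neuronal gene was higher (cpo) and 2 were lower (Appl and Rbp9), and 2 midgut markers were lower. With that block 1 glial marker was higher and 2 were lower, 2 neuroblast markers and 2 cuticle genes were higher, 1 muscle marker was higher and 1 lower, 1 fat body marker and 1 ribosomal protein gene were higher, and 1 germline marker was higher and 1 lower. The genes named with the block were chosen after their values were seen.

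**Figure D2:**
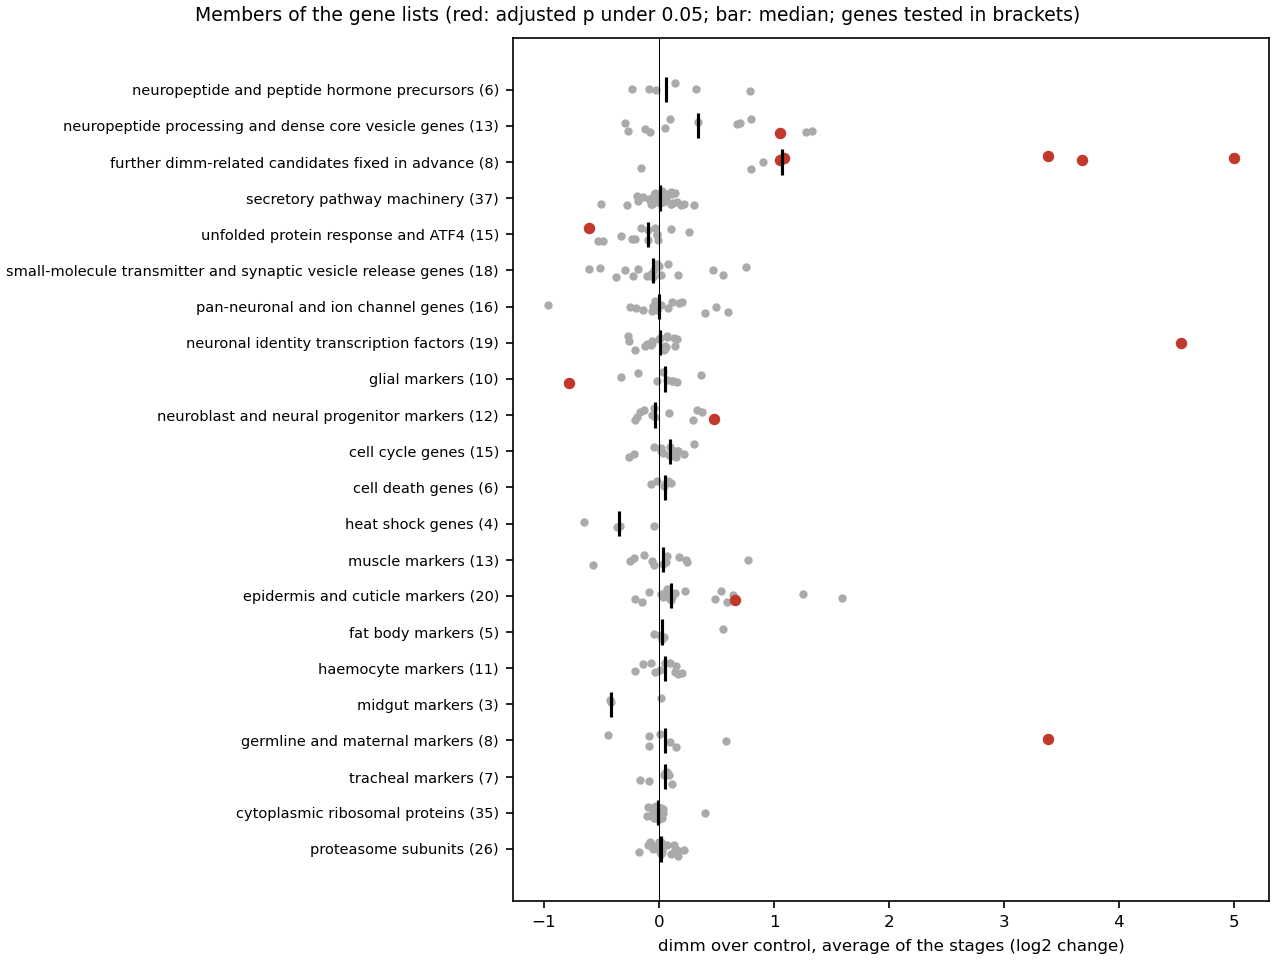
Log2 change of dimm over control, averaged over the stages, for each tested member of the gene lists (points, red where the adjusted p was under 0.05), with the median of each list as a bar and the number of genes tested in brackets. The medians of the neuropeptide processing list and of the further candidates are 0.34 and 1.07, and red points number 1 and 5 in them.

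At stage 14 alone, CngA rose by 6.28 ± 0.08, GILT3 by 5.82 ± 0.16, Hrb87F by 5.79 ± 0.18, Rnf11 by 5.12 ± 0.46 and CG33258 by 4.84 ± 0.28 on the log2 scale (2 arrays against 2). CG9498 fell by 1.42 ± 0.14, GstE1 fell by 1.21 ± 0.09, and jhamt, the juvenile hormone acid methyltransferase gene, fell by 0.69 ± 0.07. In limma 28 probe sets passed, 24 higher and 4 lower. With signals below 4 raised to 4, the rise of CngA was 4.46, that of CG33258 3.51 and that of GILT3 5.50. The control arrays of CngA lay at the floor, where arrays hardly vary, so its error of 0.08 may be too small. The candidate list, drawn in part from published work on these samples, had 2 of 8 higher, and 6 with the replicate pairs as a block. Its set test (adjusted p = 9.41e-10 by camera, adjusted p = 0.0528 with an estimated correlation) is thus not independent evidence. No single cell cycle gene passed, but 14 of 15 changes were positive and the set was higher by camera (adjusted p = 0.0137, and adjusted p = 0.923 with an estimated correlation). The unfolded protein response list was lower (adjusted p = 0.00903, and adjusted p = 0.777 with an estimated correlation). With the replicate pairs as a block 157 probe sets passed, although same-numbered arrays of stage 14 shared little (correlation of deviations 0.155). With a replicate term for stage 16 alone, which pairs no stage 14 arrays, 312 passed. That term takes the stage 16 replicate difference out of the spread used for both stages. Leaving out any single array gave 3 to 25, and leaving out both low 5' arrays of stage 16 gave 74.

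At stage 16 alone, Hrb87F rose by 6.17 ± 0.18, GILT3 by 5.73 ± 0.16, Rnf11 by 4.89 ± 0.46, mael by 4.51 ± 0.33 and CG4577 by 3.94 ± 0.25. TM4SF fell to 0.214 of the control level, CG8160 fell by 1.97 ± 0.22, Npc2e, a sterol-binding protein family gene, fell by 1.77 ± 0.15, CG4440 fell by 1.41 ± 0.13 and GstE1 fell by 1.15 ± 0.09. In limma 30 probe sets passed, 18 higher and 12 lower. That fit takes 1 spread per probe set for both stages, although control arrays differed more at stage 16 (SD 0.798) than at stage 14 (0.165). The stage 16 errors thus borrow precision from stage 14. With the stage 16 arrays alone 2 probe sets passed, 2 higher and 0 lower, and with array weights 0 passed. With signals below 4 raised to 4, the rise of GILT3 was 4.72, and the fall of CG8160 did not pass. The candidate list, drawn in part from published work on these samples, had 3 of 8 higher, and 7 with the replicate pairs as a block. Its set test (adjusted p = 3.89e-12 by camera, adjusted p = 0.0348 with an estimated correlation) is thus not independent evidence. The neuropeptide processing list was higher by camera (adjusted p = 0.00186, and adjusted p = 0.26 with an estimated correlation), with none of 13 past over all genes, 4 higher when adjusted over the list alone and 4 higher over all genes with the replicate pairs as a block. With the replicate pairs as a block 219 probe sets passed, 110 higher and 109 lower, and the epidermis and cuticle list was higher by camera (adjusted p = 0.0179). Without the block that list did not pass (adjusted p = 0.128, and adjusted p = 0.639 with an estimated correlation), nor did it without the low 5' arrays (adjusted p = 0.277). Leaving out both low 5' arrays gave 406, with more lower (248) than higher (158), a replicate term for stage 16 alone gave 334 higher and 407 lower, and leaving out any single array gave 2 to 13.

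The rises at the 2 stages shared members. Of the 24 probe sets higher at stage 14 and the 18 higher at stage 16, 12 were the same, and of the 4 and 12 lower, 1 was the same. None passed in opposite directions. The stages share no arrays, but the fit gives each probe set 1 spread for both, which favours shared calls, so no test of the overlap is given. Across all tested probe sets, the changes at the stages had a Pearson correlation of 0.565 and a Spearman correlation of 0.474. This correlation is across genes, which are not independent replicates.

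**Figure D3:**
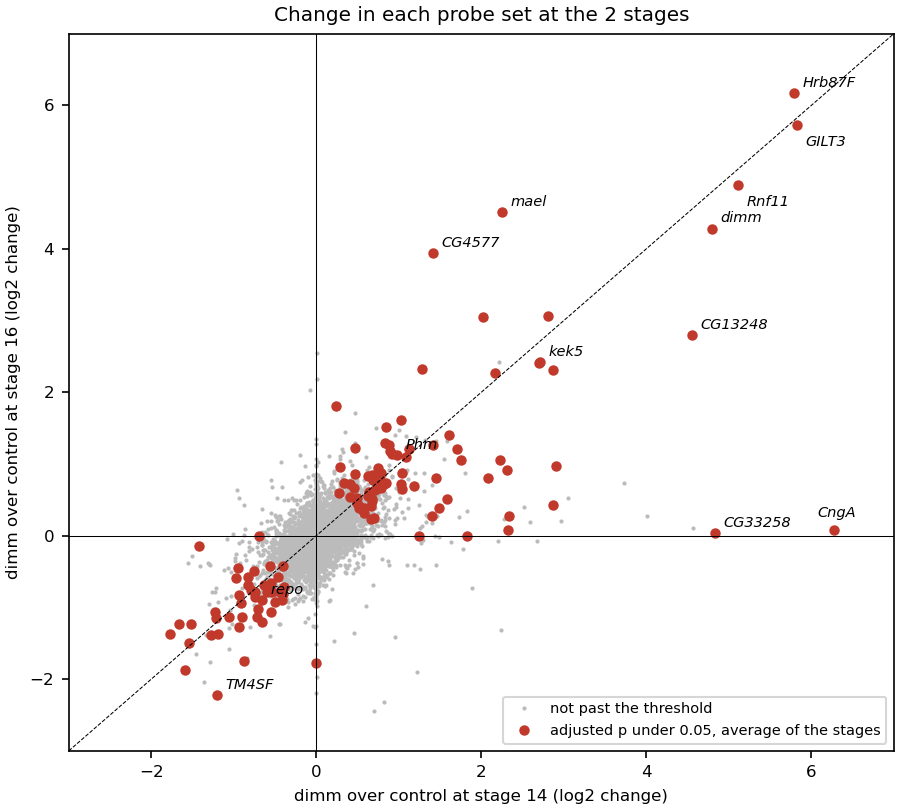
Log2 change of dimm over control at stage 14 (horizontal axis) and at stage 16 (vertical axis) for each of 8258 probe sets, with those past the threshold on average in red and the line of equal change dashed. Hrb87F, GILT3, Rnf11 and dimm lie near that line, while CngA and CG33258 lie near 0 at stage 16.

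The effect of dimm differed between the stages for 1 probe set. CngA rose from the lowest value to 8.46 at stage 14, and was 3.45 in control and 3.54 in dimm embryos at stage 16, so its effect was lower at stage 16 by a log2 difference of -6.19 ± 0.11 (adjusted p = 8.63e-05 in limma). All values but those of dimm embryos at stage 14 lay below 4, and with such values raised to 4 the difference was -4.46, so its size is uncertain. Arrays at the floor hardly vary, so the error (against a median of 0.25 over all probe sets) and the adjusted p may be too small. The corresponding difference for CG33258, whose means also lay below 4 except in dimm embryos at stage 14, was -4.79 ± 0.39 (adjusted p = 0.103), and for CG4577 it was 2.52 ± 0.36 (adjusted p = 0.615). By unadjusted p under 0.05, 249 probe sets were counted. With the replicate pairs as a block 3 passed, and without the low 5' arrays 38. Camera gave a difference for 4 lists. The change at stage 16 was higher for neuropeptide processing genes (adjusted p = 0.0151) and for epidermis and cuticle genes (adjusted p = 0.0466), and lower for cell cycle genes (adjusted p = 0.0149) and heat shock genes (adjusted p = 0.0237). With the replicate pairs as a block the call of the heat shock genes was lost (adjusted p = 0.169), while the other lists kept theirs (adjusted p = 0.0229). With 1 replicate term over both stages, 3 of the 4 lists kept their call. None held with an estimated correlation (adjusted p = 0.583 for the first pair and adjusted p = 0.701 for the second), and none held without the low 5' arrays.

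Between stage 14 and stage 16 of the control line, muscle and cuticle genes rose and cell cycle genes fell. All 13 muscle markers rose (median 2.40), among them Prm, the paramyosin gene, by 4.17 ± 0.33 and Mlp60A by 3.71 ± 0.29. Of 20 epidermis and cuticle genes 14 rose, including Ccp84Ac (6.35 ± 0.13), TwdlG (5.99 ± 1.07) and TwdlM (6.77, adjusted p = 0.0217, a call lost in 5 of 21 alternative settings). Over all genes, the 5 largest rises by the naming rule were those of CG3108 (8.65 ± 0.37), CG17127 (7.56), CG8160 (7.49), CG17290 (7.73 ± 2.09) and the cuticle protein gene Lcp65Ag3 (8.79 ± 2.73, adjusted p = 0.0362). The call of Lcp65Ag3 was lost in 9 of 21 alternative settings and that of CG17290 in 5, and their errors leave the order open. Of 18 transmitter and synaptic genes 13 rose, including ChT (5.31), Vmat (5.28), the dopamine transporter gene DAT (4.69) and Gad1 (4.33), and of 16 pan-neuronal genes 9 rose and 1 fell. Of 6 neuropeptide precursors 5 rose, including Mip (3.93) and Pdf (2.96), and ITP fell by 0.37 ± 0.10, a fall that did not pass after median centring. Of 13 neuropeptide processing genes 8 rose, including IA-2 (6.66) and amon (4.58). Of 15 cell cycle genes 12 fell and 1 rose, with fzy, the Cdc20 gene, at -4.67 and aurB at -3.71, and 9 of 12 neuroblast markers fell, including ase at -2.31 and cas at -2.15. The largest falls were those of jhamt (-8.17), CG13064 (-7.28), the transcription factor gene Blimp-1 (-6.59), MFS1 (-6.07) and CG34224 (-5.81).

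In other lists of this comparison, 7 of 10 glial markers, 12 of 37 secretory pathway genes, 4 of 6 cell death genes and 4 of 8 germline markers fell, while 1 cell death gene and 1 germline marker rose. In the unfolded protein response list 2 rose and 7 fell, among transcription factors 3 rose and 5 fell, in the candidates 2 rose and 2 fell, among haemocyte markers 4 rose (including the collagen genes Col4a1 and vkg) and 2 fell, and in the fat body and tracheal lists 1 rose and 1 fell. One of 3 midgut markers and both sensory organ genes rose, msl-2 fell, and no heat shock or antimicrobial peptide gene passed. Of 26 proteasome genes 14 fell, and of 35 ribosomal protein genes 2 rose and 4 fell. Many of these counts moved with the scaling. After each array was centred on its median, 4 proteasome genes fell, 22 ribosomal protein genes rose and 2 fell, 6 secretory genes fell and 1 rose, 4 genes of the unfolded protein response rose and 3 fell, and 4 glial markers fell. Under that centring 4 fat body markers rose and 1 fell, 3 tracheal markers rose and 1 fell, 4 haemocyte markers rose and none fell, 2 midgut markers rose, and msl-2 did not pass. The block of replicate pairs gave further movements: 22 secretory genes fell and 2 rose, 14 transcription factors fell and 4 rose, 4 pan-neuronal genes, 4 tracheal markers and 4 haemocyte markers fell, 2 midgut and 2 fat body markers rose, both genes of sex chromosome dosage fell, and 2 genes each of the neuropeptide processing, transmitter and cuticle lists fell.

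In all, 5023 probe sets passed between the stages in control embryos, 1799 higher and 3224 lower, and 5245 in dimm embryos, 1713 higher and 3532 lower. The median change over all tested probe sets was -0.38 in control and -0.44 in dimm embryos. After median centring the split was 2177 higher and 2471 lower in control, and 2260 higher and 2487 lower in dimm embryos. In camera 10 lists passed in control embryos (adjusted p from 2.05e-06 for muscle to 0.0494 for ribosomal protein and proteasome genes), and none held with an estimated correlation (adjusted p from 0.215 to 0.695 for these). The lowest value was 2.18160 on all stage 14 arrays and 2.18606 on all stage 16 arrays, and whether the stages were processed together is not given in the sources used here. A difference in processing, if there was one, cannot be told apart from stage in these changes. Low 5' signal on the replicate 1 arrays of stage 16 also enters them. For the 5' actin control probe set, the control arrays lay at 4.72 and 10.04 at stage 16, and at 11.3 and 11.1 at stage 14. How far this adds to the falls was not counted.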

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

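The tests of 5' signal loss, of neighbouring genes and of other probe sets, the use of splits balanced over the stages, and the slope that followed the correlation with the stage axis, were chosen after the results they bear on had been seen. No group had enough arrays for a test of single outlying arrays.

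The effect of dimm on CngA differed between the stages, with a log2 difference of -6.193 (stage 16 minus stage 14, limma's test of that difference). The control arrays of stage 14 lay at the lowest value, where arrays hardly vary, so the error of that test may be too small. With values under 4 raised to 4 the difference was -4.46. For lists, camera's test of the difference between the stages gave an adjusted p of 0.0151 for neuropeptide processing and dense core vesicle genes, 0.0149 for cell cycle genes, 0.0237 for heat shock genes and 0.0466 for epidermis and cuticle markers. With an estimated correlation none of these held (adjusted p of 0.583, 0.701, 0.701 and 0.583), and the heat shock call was also lost with the replicate pairs of each stage as a block (adjusted p of 0.169). The heat shock list rests on 4 genes, whose Hsp26 had an SD of 2.89 between the control arrays at stage 16.

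The replicate 1 arrays of stage 16 stood apart from replicate 2 in both genotypes. From replicate 1 to replicate 2 the 5' signal of the control transcripts rose relative to the 3' signal by 1.30 to 4.96 log2 units over 4 transcripts in the 2 genotypes, while at stage 14 it changed by -0.77 to -0.16. This fits a loss of 5' signal in RNA or labelling that was shared by both genotypes. Embryos of different age within the collection window would move the arrays along the change between stages. Across probe sets the replicate difference of the control arrays correlated at 0.0211 (bootstrap SE 0.012) with the stage change of dimm arrays. That of the dimm arrays correlated at 0.0521 (SE 0.014) with the stage change of control arrays. The bootstrap resampled probe sets, not embryos. Both correlations lie under the bound of 0.1 set in advance. However, each stage change used the stage 16 replicate 2 array of the other genotype, which shares that replicate's deviation (correlation 0.906). That sharing lowers both correlations, so they cannot decide whether age was a source. By SD of the difference, control replicate 1 lay farther from the stage 14 control arrays (1.88 and 1.89) than replicate 2 (1.68 and 1.69). The dimm arrays went the same way (1.83 and 1.89 against 1.69 and 1.74). No other biological explanation was tested, since the design gives no group for it.

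A further pattern is the 124 probe sets that differed between genotypes. Of the 18 splits of the 8 arrays with 2 arrays of each stage on each side, 1, the real one, gave as many probe sets (153 in an additive fit, 0 in the highest other split), and 18 splits are too few for a share under 5%. The share depends on the splits allowed. It was 2.94% over all 34 fitted splits, many of them unbalanced over the stages, and 12.5% over the 8 that part all same-numbered arrays of a stage. Single probe sets rather than transcripts stay open: 7 of 7 other probe sets of 6 called genes moved the same way, with a median ratio of 0.635 to the size of the first. However, 1 of the 7 passed, that of Rnf11, and 6 of 107 called genes is a small part. The other probe set of Phm passed only with the replicate pairs as a block (adjusted p = 0.0158 in limma). An extended chromosomal difference between the parental strains stays open: 3 pairs of neighbouring genes changed the same way (Ciao1 with HPS1, CG32032 with CG13315, CG14419 with CG3588), against a mean of 0.91 in 10000 random placements (one-sided permutation p = 0.0627). Expression of dimm, GAL4 dose and paternal background differ together between the groups and cannot be told apart by this design.

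Another pattern is the change of cell cycle genes in dimm over control embryos, which was higher at stage 14 than at stage 16. If the dimm embryos of stage 14 were younger, their difference from control should oppose the change from stage 14 to stage 16 over all probe sets, at a correlation below -0.1. With control arrays split so that none was shared, the correlations were 0.0203 (bootstrap SE 0.022) and 0.0753 (SE 0.020). The slopes were 0.00415 and 0.0152, where the cell cycle genes alone would need -0.123 and -0.205. However, the 2 control arrays of stage 14 correlated at 0.9995 and may be of 1 RNA sample. A deviation they share enters both sides with the same sign, which raises both correlations and both slopes. These values therefore cannot decide whether a younger collection was a source, and the first correlation lies within its error of 0. The expression of dimm itself remains open, and the list's call was lost with an estimated correlation.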

How the results depend on the processing

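The replicate block within each stage, the batch term for stage 16, and leaving out both low 5' arrays were chosen after the data were seen. Over 143 named changes and the settings tried, 2527 values kept their direction and side of the threshold, 474 lost the call, 2 gained it and 2 changed sign. The 2 are those of elav, at -0.00758 without control stage 16 replicate 1 and -0.00525 without dimm stage 16 replicate 2, and its highest value was 0.0501 without control stage 16 replicate 2. Neither is past the threshold. Many of the 143 are stage changes in control embryos, so the totals say little of the dimm effect. The average rises of Hrb87F and GILT3 passed under all 22 settings, and that of CG13248 lost its call in 3. The average call was lost in 10 of 22 settings for dimm, 11 for repo, 12 for AsnS and 15 for pros. The stage 16 call was lost in 13 of 21 for TM4SF, 12 for GstE1 and 10 of 20 for mael, against 1 of 21 each for Hrb87F and GILT3. The cause of these movements was not tested. Dim probe sets near the floor limit what can be measured: 6 of 37 neuropeptide precursors could be tested. Groups of 2 arrays allow no Dixon test.

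For dimm over control, average, stage 14, stage 16 and the difference between stages gave 124, 28, 30 and 1 probe sets. The average gave 44 with no filter, 80 with 1 replicate block term over both stages, 3 with arrays averaged, 43 with array weights, 53 at 2-fold, 639 with the replicate block within each stage, 1129 with the batch term and 816 without the low 5' arrays. Stage 14 gave 17 with 1 replicate block term, 74 with its own arrays alone, 734 with array weights, 157 with the replicate block within each stage, 312 with the batch term and 74 without the low 5' arrays. Stage 16 gave 4 with no filter, 2 with 1 replicate block term, 2 with its own arrays alone, 0 with array weights (658 at an unadjusted p under 0.05 in the limma fit as reported), 219 with the replicate block within each stage, 741 with the batch term and 406 without the low 5' arrays. The difference gave 5 with no filter, 3 with signals under 4 set to 4, 3 with the replicate block within each stage, 10 with the batch term and 38 without the low 5' arrays. All 124, 28 and 30 calls were kept under the replicate block within each stage. That block leaves each change between genotypes as it was and alters only its spread, so no direction could change.

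Leaving out 1 array gave 4 to 66 for the average, 3 to 25 for stage 14, 2 to 13 for stage 16 and 1 to 2 for the difference. The average was 4 without either control stage 14 array, 17 and 15 without dimm stage 14 replicates 1 and 2, 51 and 66 without control stage 16 replicates 1 and 2, and 51 and 48 without dimm stage 16 replicates 1 and 2. Stage 14 was 3 without either control stage 14 array, 6 without either dimm stage 14 array and 11 without either control stage 16 array. Stage 16 was 2 without either control stage 14 array, 3 without either dimm stage 14 array, 7 and 10 without control stage 16 replicates 1 and 2, and 13 and 8 without dimm stage 16 replicates 1 and 2. The difference was 2 without either dimm stage 14 array, control stage 16 replicate 2 or dimm stage 16 replicate 1. A lone array was assumed to vary like the other groups. The stage change ranged from 3648 to 5394 in control and from 3958 to 5708 in dimm embryos. With no filter it was 14601 and 14766, and at 2-fold 3149 and 3375. Without the filter, background values enter, whose floor differs between the stages, but their share of the added calls was not counted.

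Lists past the threshold in camera numbered 3 for the average, 3 at stage 14, 2 at stage 16, 4 for the difference, and 10 and 9 for the stage change in control and dimm embryos. With an estimated correlation they numbered 1, 0, 1, 0, 0 and 0, and with fry 1, 1, 1, 0, 17 and 17. Without the low 5' arrays the average, stage 14, stage 16 and the difference had 1, 1, 1 and 0, and with the replicate block within each stage the average had 1. The replicate block moved the number of no other list comparison by more than 1.5 times.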

Other observations

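The genes below were chosen after their values were seen, and all are among those past the threshold for the average effect in limma. Several genes with known roles in neurons fell in dimm embryos: nAChRbeta1, an acetylcholine receptor subunit gene, fell by 0.52 ± 0.06, RIC-3, a chaperone gene for such receptors, fell by 0.88 ± 0.08, wit, the BMP type II receptor gene of motor and peptidergic neurons, fell by 0.49 ± 0.07, and jim, a zinc finger gene, fell by 0.77 ± 0.08. PICK1, whose product acts in the formation of dense core vesicles, rose by 1.07 ± 0.09, from 4.41 to 5.29 at stage 14 and from 5.27 to 6.53 at stage 16. Other probe sets of these genes did not pass: that of nAChRbeta1 differed by -0.22 (adjusted p = 0.912), and those of jim by -0.38 and -0.49 (adjusted p = 0.535 and 0.705). Grp170, an endoplasmic reticulum chaperone gene, rose by 0.58 ± 0.06, RabX4, a small GTPase gene, by 0.62 ± 0.07, and Vps13 by 0.76 ± 0.06.

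Besides mael, the Tudor domain gene Veneno rose by 1.46 ± 0.11 and MAGE by 1.34 ± 0.09. Among genes of detoxification, Cyp12c1 (1.65 ± 0.23), Cyp9c1 (1.02 ± 0.13), Cyp6a8 (0.83 ± 0.11) and GstD5 (1.31 ± 0.12) rose, while GstE1 fell by 1.18 ± 0.07. NLaz, a lipocalin gene, rose by 1.07 ± 0.15, and santa-maria, a scavenger receptor gene, by 1.05 ± 0.10. None of these groups was tested for enrichment.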
